A study of Sus scrofa with 12 samples.

How the data were processed

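Endometrium was collected from 12 sows on Day 14 after insemination, 6 pregnant and 6 that had been inseminated with inactivated semen and were not pregnant. Each group held 3 Yorkshire and 3 Landrace sows. Per the labels' protocols, both uterine horns were flushed with phosphate-buffered saline and fetal calf serum, tissue was taken from the upper, middle and lower part of each horn without the muscle layer, and total RNA was isolated with TRIzol and hybridised as biotinylated cRNA to Affymetrix porcine arrays, 1 array per sow. Flushing removes loose conceptuses from the lumen, and whatever stayed attached would be measured with the tissue.

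The deposited values are log2 expression values per probe set. RMA and the affy and limma packages are named in the submitters' processing notes, without versions. RMA corrects the background, makes the intensity distributions of the arrays alike and combines the probes of a set on the log2 scale, and the deposited columns have nearly the same distribution on all 12 arrays, with medians between 6.25 and 6.30. Because the distributions were made alike, a change of total RNA output per sow could not be measured, and differences are relative to the other probe sets of the same array. Values near the lower end of the scale hold mostly background, which makes fold changes of weakly expressed genes too small. RMA values carry no count of molecules, so the number of arrays limits the precision. The table held 24123 probe sets, of which 124 manufacturer controls were left out of the tests, leaving 23999.

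Gene symbols came from a platform annotation table, in which 10069 of the tested probe sets had 1 symbol, 198 had several and 13732 had none. Probe sets with several symbols or none were counted but not named. Of the probe sets with 1 symbol, 9961 had a gene identifier found in the RefSeq gene table of the assembly Sscrofa11.1, which changed 0 symbols. No genome build was given for the array design in the sources used here, so no coordinates are reported. Where a gene had several probe sets, which was so for 2261 of 6765 genes, the probe set with the highest mean over the 12 arrays stood for the gene.

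Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 23999 probe sets and a threshold of adjusted p under 0.05. The pregnancy effect was fitted over all 12 arrays with breed as an additive term, which left 9 residual degrees of freedom, and the breed effect came from the same fit. The pregnancy effect within each breed and the pregnancy by breed interaction came from a fit of 4 groups over the same arrays with 8 residual degrees of freedom. Shifts of gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists that had at least 5 measured members, and again with an estimated correlation and with the rotation test fry. Of the 821 names on 20 gene lists and 14 cell type lists, 545 were measured. The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls among called genes, up to 4 called members of each list with the smallest p (2 members where none was called), the 18 measured genes of a fixed set of 20, and for breed the 5 largest called differences each way. Where no gene was called for the interaction, the 3 with the smallest p were named. AKR1B1 had no probe set under that name and was not analysed here.

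Each sow is 1 replicate, and the labels describe separate animals. The labels name no pairs, and the replicate numbers were not shared between the groups, so no pairing was fitted. The numbers alternate between the groups, and each non-pregnant sow shares its breed with the pregnant sow of the next number. Whether this order reflects pairs or processing was not tested. The procedure was tested on simulated data with the real probe set means and spreads and 200 changed probe sets among 23999. The noise was drawn independently for each probe set. In the real data the estimated correlation within a list reached 0.755, so the shares that follow may not hold for the real arrays. At a log2 change of 1 it recovered 98.5% of the changed probe sets for pregnancy, 85.1% for breed, 83.6% within Yorkshire, 80.6% within Landrace and 50.7% for the interaction. At a log2 change of 0.5 the recovered shares were 62.7% for pregnancy, 68.7% for breed, 16.4% within Yorkshire, 17.9% within Landrace and 2.99% for the interaction. Among calls, 3.37% were false for pregnancy and 4.41% within Landrace. Alternatives were a second normalization by cyclic loess, centring each array on its median, leaving out dim probe sets (those not above the median of all values on at least 3 arrays), an intensity trend with a robust prior, array weights, no breed term, the average of both within-breed contrasts, the first residual component as a covariate, stricter thresholds, other list tests and leaving out each sow in turn. Leaving out non-pregnant sow 7 and pregnant sow 10 together, and leaving HSPA8 out of the stress list, were added after seeing the data.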

Results

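The data were log2 expression values of 23999 probe sets from the endometrium of 12 sows, 6 pregnant and 6 non-pregnant, with 3 Yorkshire and 3 Landrace sows in each group. The array of each sow correlated with its nearest array at r of 0.975 to 0.992, across probe sets, which are not independent. The first principal component held 36.8% of the variance and was higher in pregnant than in non-pregnant sows by 39.62 on average (exact permutation p = 0.0260, two-sided, n = 6 per group). The second component held 17.3% and was higher in Landrace than in Yorkshire sows by 28.28 (exact permutation p = 0.00433), and it also differed by -23.66 between pregnant and non-pregnant sows (exact permutation p = 0.0476). Non-pregnant sow 7 lay at 20.4 on the first component and 43.5 on the second, away from the other non-pregnant sows, and pregnant sow 12 lay at -18.9 on the first, and the array with which it correlated most was that of non-pregnant sow 11. The difference between 3' and 5' GAPDH control probe sets, a sign of RNA integrity, was 1.36 ± 0.204 in pregnant and 1.20 ± 0.289 in non-pregnant sows (SD, n = 6 each, exact permutation p = 0.273), and it was lower in Landrace than in Yorkshire sows (difference -0.421, exact permutation p = 0.00217).

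**Figure D1:**
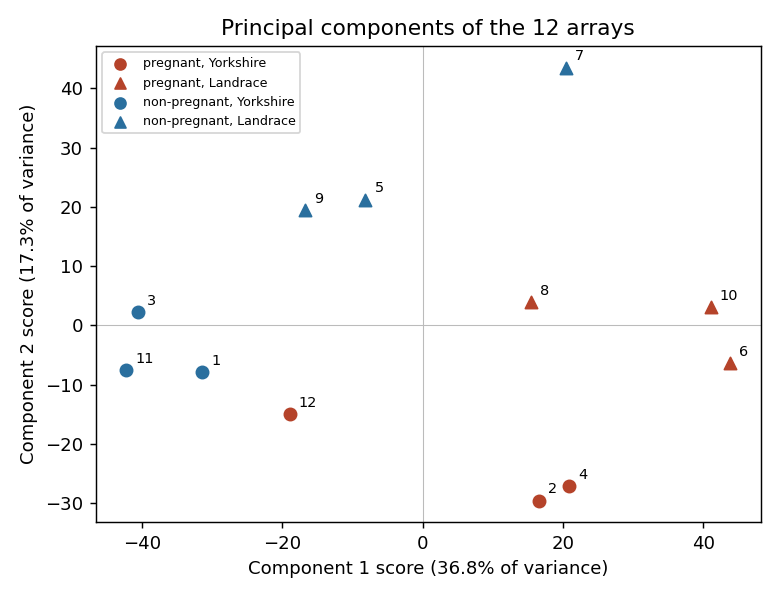
Each point is the array of 1 sow on the first 2 principal components of all tested probe sets, in arbitrary component units, coloured by pregnancy and shaped by breed. The first component holds 36.8% of the variance and separates most pregnant from most non-pregnant sows, with pregnant sow 12 and non-pregnant sow 7 nearer to the other group.

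The first comparison asked which transcripts of the endometrium differ between pregnant and non-pregnant sows on Day 14. The largest rise was in S100A9, a calcium-binding protein of neutrophils and stressed epithelium, at 11.58 ± 1.91 in pregnant and 4.53 ± 2.38 in non-pregnant sows (mean ± SD of log2 values, n = 6 each, adjusted p = 0.00517). The log2 difference of 7.05 was 7.95 without non-pregnant sow 7 and 7.73 without pregnant sow 12. The S100A9 values of the other 5 non-pregnant sows, 3.16 to 3.91, the NPY values of all 6, 3.48 to 3.78, and the SERPINB7 values of 4 of them, 3.01 to 3.21, lay below the lower quartile of every array, so background limits how exactly these differences are known. TRPV6, an epithelial calcium channel, rose by 3.07 ± 0.42 on the log2 scale (SE, adjusted p = 0.00457), and GPX3, a secreted glutathione peroxidase, by 2.60 ± 0.29 (adjusted p = 0.00185). The cell-surface protein EMB, the neuropeptide NPY and IGFBP2, which binds insulin-like growth factors, rose by 3.52, 3.21 and 2.17. For TRPV6, GPX3, EMB, NPY and IGFBP2 every pregnant sow lay above every non-pregnant sow. SERPINB7, a serine protease inhibitor, rose by 3.90, KMO of the kynurenine pathway by 2.42, the membrane mucin MUC4 by 2.42 and FGL2 by 2.10, each higher in 6 of 6 pregnant sows than the non-pregnant mean. NMB rose by 2.34 (adjusted p = 0.0263) and STC1, a secreted regulator of calcium and phosphate, by 2.29 (adjusted p = 0.0332, higher in 5 of 6 sows). The NMB call ended when any 1 of non-pregnant sows 1, 3, 9 and 11 or pregnant sows 2, 4 and 10 was left out, with adjusted p up to 0.0639, and the STC1 call when any 1 of pregnant sows 2, 4, 6 and 10 or non-pregnant sows 3, 5, 9 and 11 was, with adjusted p up to 0.0781. The other 10 rises were called in each of the 12 fits that left out 1 sow.

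Among the falls, the antimicrobial peptide DEFB1 fell by 2.76 ± 0.67 on the log2 scale (SE, adjusted p = 0.0275) and the vesicle GTPase RAB26 by 2.59 ± 0.70 (adjusted p = 0.0432), both lower in 5 of 6 pregnant sows than the non-pregnant mean. The water and glycerol channel AQP3 fell by 2.52 ± 0.49 (adjusted p = 0.0124), BCAT1, which acts on branched-chain amino acids, by 2.29 ± 0.38 (adjusted p = 0.00708) and CALML4 by 1.71 ± 0.32 (adjusted p = 0.0116), each lower in 6 of 6 sows and each called in every fit that left out 1 sow. The other called falls were MFAP5 at a log2 difference of -2.30, TMEM100 at -2.03, ATP6V0D2 at -1.75, LOC100157017 at -1.74, CYP2C91 at -1.69, VWA5A at -1.63 and NAAA at -1.62. Of the 24 largest changes, which were called genes chosen for their size, 6 had no overlap between the groups. For a gene that does not differ between the groups, chance gives no overlap in 0.216% of cases. The share among all measured genes is not given here, so the 6 cannot be set against it. The calls of the falls were closer to the threshold than those of the rises. VWA5A lost its call without pregnant sow 2 (adjusted p = 0.0539), MFAP5 without pregnant sow 2 or 6 or non-pregnant sow 9 (adjusted p up to 0.0541), and DEFB1, RAB26, TMEM100, ATP6V0D2, LOC100157017, CYP2C91 and NAAA each without at least 7 of the 12 sows taken singly, with adjusted p up to 0.0967 for RAB26.

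**Figure D2:**
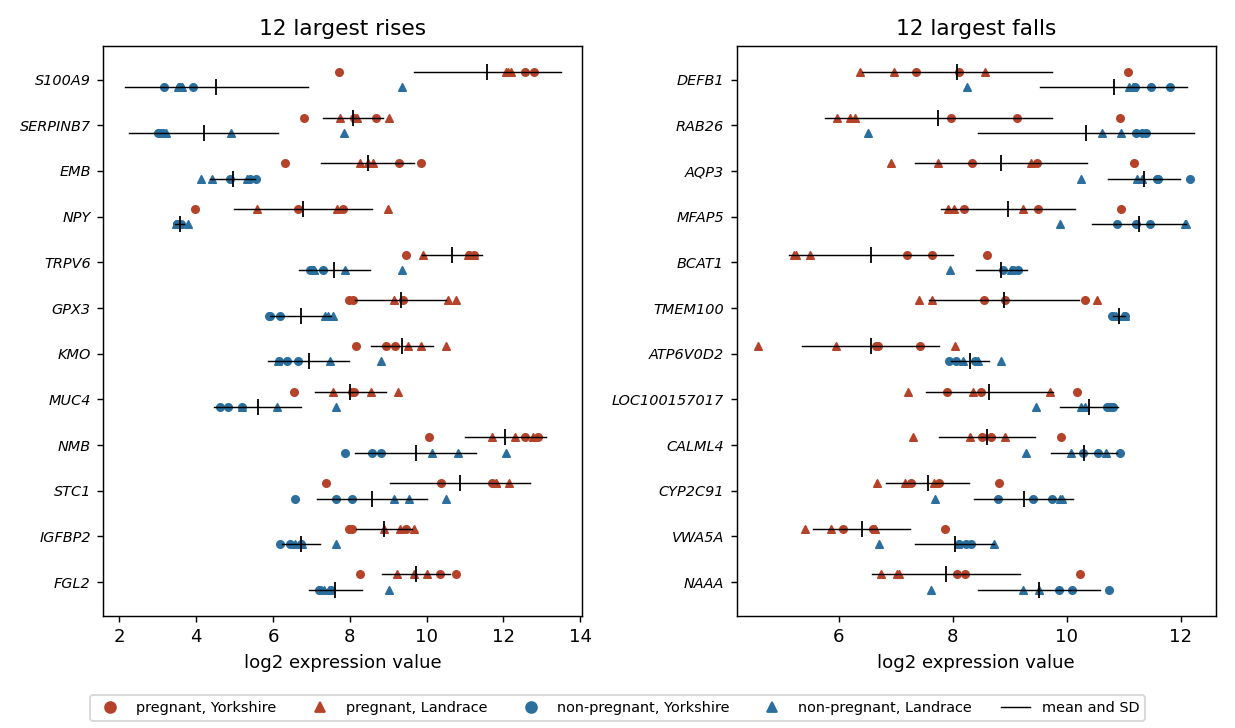
Log2 expression values of the 12 genes with the largest called rises and the 12 with the largest called falls, 1 point per sow, with vertical ticks for group means and horizontal bars for SD (n = 6). S100A9 lies at 7.72 in pregnant sow 12 and 9.35 in non-pregnant sow 7, apart from the other sows of their groups.

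Most measured endothelial markers rose. Of the 10 measured markers of endothelium, 7 rose over all genes tested and 10 when adjusted over the list alone, and none fell. The clotting factor carrier VWF rose by 0.91 ± 0.18 on the log2 scale (SE, adjusted p = 0.0127, with 1 of its 2 other probe sets showing the same sign), the junction protein CDH5 by 0.92 ± 0.19 (adjusted p = 0.0146), the transcription factor ERG by 0.71 and the receptor TIE1 by 0.54, each with every pregnant sow above every non-pregnant sow. The mean of the list, relative to the non-pregnant mean, lay between 0.351 and 0.867 in pregnant and between -0.277 and 0.209 in non-pregnant sows. The list was called (camera, adjusted p = 2.28e-07), but not with an estimated correlation (adjusted p = 0.206 with an estimated correlation). On the list of angiogenesis and vascular permeability 5 of 22 measured members rose by 0.519 to 0.648, the receptors KDR, TEK, TIE1, EDNRB and S1PR1, and 5 when adjusted over the list alone (list adjusted p = 0.000446, adjusted p = 0.274 with an estimated correlation). KDR, TEK and TIE1 stand on both lists. The calls of EDNRB, TEK and KDR ended without any 1 of 5, 7 and 9 sows, with adjusted p up to 0.0862. The endothelium count was 4 without any 1 of non-pregnant sows 1, 3, 9 and 11 or pregnant sows 2, 4 and 6. The angiogenesis count was 1 to 3 without any 1 of non-pregnant sows 1, 3, 5, 9 and 11 or pregnant sows 2, 4, 6 and 10.

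Some stromal, matrix and smooth muscle transcripts were higher in pregnant sows. Of 29 measured genes of extracellular matrix and remodelling, 4 rose and 6 when adjusted over the list alone, with none falling. They included the gelatinase MMP2 at 0.57 ± 0.08 on the log2 scale (SE, adjusted p = 0.00464) and the basement membrane collagen COL4A2 at 0.82 ± 0.15 (adjusted p = 0.0110). Of 10 measured stromal fibroblast markers, 4 rose, among them the intermediate filament VIM by 0.65 (adjusted p = 0.00468) and the surface antigen THY1 by 1.37 (adjusted p = 0.00906), and DPT fell by 0.848, which were also the counts adjusted over the list alone. Of 10 smooth muscle markers, MYL9 rose by 0.37 and 4 rose when adjusted over the list alone. The adjusted p of these lists was 0.000446 for matrix, 0.00521 for stroma and 0.000923 for smooth muscle, and 0.410, 0.410 and 0.274 as adjusted p with an estimated correlation. The MYL9 call ended without any 1 of 9 sows, with adjusted p up to 0.0954, and the smooth muscle count was 2 without pregnant sow 10. The matrix count was 2 without non-pregnant sow 3 or pregnant sow 2, 4 or 6, and BGN and DCN lost their calls without any 1 of 5 and 7 sows (adjusted p up to 0.0602 and 0.082). The count of stromal rises was 2 without any 1 of non-pregnant sows 1, 3 and 5 or pregnant sows 2, 4 and 6, where DCN and PDGFRB (adjusted p up to 0.0867) lost their calls. The fall of DPT was not called without any 1 of 9 sows.

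Genes of the luminal epithelium that respond to conceptus oestrogen, secreted proteins of the uterine lumen and adhesion molecules rose in part. On the list of conceptus oestrogen-responsive luminal genes, 5 of 14 measured members rose by 0.846 to 2.42, namely STC1, FGF9, NMB, MUC4 and CST6, and none fell; adjusted over the list alone, 5 rose and 1 fell. The growth factor FGF9 rose by 1.10 ± 0.18 on the log2 scale (SE, adjusted p = 0.00673), with no overlap between the groups. SPP1, the secreted integrin ligand osteopontin, differed by 0.07 ± 0.73 (adjusted p = 0.972). Its value was 12.2 in non-pregnant sow 7 and 7.3 to 8.1 in the other non-pregnant sows. Without non-pregnant sow 7 the difference was 0.902 and its adjusted p 0.0123. Leaving out the highest non-pregnant sow raises the difference by construction. Log2 differences of FGF7, LPAR3, KLK1 and S100G were -0.15, 0.35, 0.00 and 0.36, and none passed the threshold (adjusted p = 0.915, 0.751, 0.990 and 0.786). IL11RA differed by -0.74 (adjusted p = 0.102) and passed without non-pregnant sow 7 or pregnant sow 8 or 12, with adjusted p of 0.0405 to 0.0465. The list was called at adjusted p = 0.00935 and reached adjusted p = 0.410 with an estimated correlation. Its count of rises was 2 or 3 without any 1 of non-pregnant sows 1, 3, 5, 9 and 11 or pregnant sows 2, 4, 6 and 10, and 1 member fell without non-pregnant sow 7 or pregnant sow 8 or 12.

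Of 25 measured histotroph proteins and protease inhibitors, 5 rose by 0.315 to 1.3 and 7 when adjusted over the list alone. The iron-binding secreted phosphatase ACP5 (uteroferrin) rose by 1.05 ± 0.25 on the log2 scale (SE, adjusted p = 0.0287) and the retinol carrier RBP4 by 1.30 ± 0.36 (adjusted p = 0.0476), and FN1, CTSD and APOA1 rose by 0.76, 0.31 and 0.52. Of 24 measured adhesion molecules and integrins, 5 rose and 2 fell, and 8 and 2 when adjusted over the list alone. The integrin subunits ITGB5 and ITGAV rose by 0.86 ± 0.09 (adjusted p = 0.00185) and 0.77 ± 0.11 (adjusted p = 0.00517), each with no overlap between the groups, and the tight junction protein CLDN7 fell by 0.47. Of 35 growth factors and receptors, 6 rose and 1 fell, and 10 and 2 when adjusted over the list alone; IGF2 rose by 0.37 and FGF12 fell by 1.38 ± 0.28 (adjusted p = 0.0134), while IGF1 differed by 0.17 (adjusted p = 0.648). The lists of histotroph, adhesion and growth factors had adjusted p of 0.00270, 0.00545 and 0.0109, and each reached adjusted p = 0.206 with an estimated correlation. The mean of the adhesion list was 0.469 in non-pregnant sow 7, against -0.193 to -0.0195 in the other non-pregnant sows. The calls of ACP5, RBP4, CTSD and APOA1 ended without any 1 of 7, 10, 8 and 8 sows, with adjusted p up to 0.071, 0.109, 0.0824 and 0.0979, and that of CLDN7 without any 1 of 6 (up to 0.0688). The histotroph count was 1 to 3 without any 1 of non-pregnant sows 1, 3 and 9 or pregnant sows 2, 4, 6, 10 and 12. The count of adhesion falls was 0 or 1 without any 1 of the sows except pregnant sow 12. Rises of growth factors numbered 3 without non-pregnant sow 5 or pregnant sow 6, and falls 4 without non-pregnant sow 7 and 2 without pregnant sow 8 or 12.

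Many measured transcripts of mitochondrial respiration fell. Of 23 measured genes of oxidative phosphorylation, 13 fell by between 0.286 and 0.58 on the log2 scale, 18 when adjusted over the list alone, and none rose. They included the complex I subunits NDUFA8 (-0.47 ± 0.08, SE, adjusted p = 0.00688), NDUFA4 (-0.46) and NDUFS7 (-0.38) and the cytochrome oxidase subunit COX5B (-0.38 ± 0.06, adjusted p = 0.00758), each with no overlap between the groups. The list mean lay between -0.456 and -0.158 in pregnant and between -0.0874 and 0.193 in non-pregnant sows. Its adjusted p was 2.28e-07 and 0.0077 with fry, and the call ended with an estimated correlation (adjusted p = 0.313 with an estimated correlation). The count of falls was 5, 7 and 6 without pregnant sows 2, 4 and 6 and 6 and 7 without non-pregnant sows 3 and 9, and 1 gene rose without pregnant sow 6.

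Genes of lipid, glucose and ion handling moved both ways. Of 28 measured genes of lipid and cholesterol metabolism, 7 fell and 2 rose, and 9 and 4 when adjusted over the list alone. HMGCS1 of sterol synthesis fell by 1.46 ± 0.21 on the log2 scale (SE, adjusted p = 0.00517), SQLE by 1.23, fatty acid synthase FASN by 0.90 and SC5D by 0.61. The list was not called (adjusted p = 0.779), and its median was 0.01 while its mean was -0.13 and the test pointed down. Of 23 genes of glucose and amino acid transport, 2 rose and 2 fell, and 2 and 3 when adjusted over the list alone. The glucose transporter SLC2A1 rose by 1.91 ± 0.23 (adjusted p = 0.00289) and ASS1 by 0.86, while the glucose transporter SLC2A3 fell by 1.48 and ODC1, of polyamine synthesis, by 1.16; the list had adjusted p = 0.600, with a median of 0.04, a mean of -0.09 and a test that pointed up. Of 19 genes of calcium and ion transport, 4 rose and 2 fell, and as many when adjusted over the list alone, with PTHLH up by 1.95 ± 0.38 (adjusted p = 0.0128), the sodium pump subunit ATP1B1 down at -1.49 and a list adjusted p of 0.359. Of 23 immediate early and stress genes, 4 fell and 7 when adjusted over the list alone, with HSPB1 at -0.77 and HSPH1 at -0.59. HSPA8 was 1 of the 4, at -0.50. Its 3 other probe sets were called in the opposite direction, so its direction is uncertain. With HSPA8 left out, 3 of 22 fell and 6 when adjusted over the list alone, and the adjusted p of the list was 0.204. The HSPH1 call ended without any 1 of 6 sows (adjusted p up to 0.0708) and that of HSP90AA1, which had a log2 difference of -0.34, without non-pregnant sow 3 (adjusted p = 0.0506). The stress list was not called (adjusted p = 0.0961), and was called without non-pregnant sow 3 (adjusted p = 0.0384), with adjusted p = 0.552 with an estimated correlation over all sows. Without that sow 2 stress genes fell, and 1 rose without non-pregnant sow 7. The count of lipid falls was 4 without any 1 of non-pregnant sows 1, 5, 9 and 11 or pregnant sows 2 and 4. That of lipid rises was 0 or 1 without any 1 of the sows except non-pregnant sow 7 and pregnant sow 12. The count of ion transport rises was 2 without non-pregnant sow 3 or pregnant sow 2, 4 or 6. That of glucose and amino acid transport falls was 4 without non-pregnant sow 7.

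**Figure D3:**
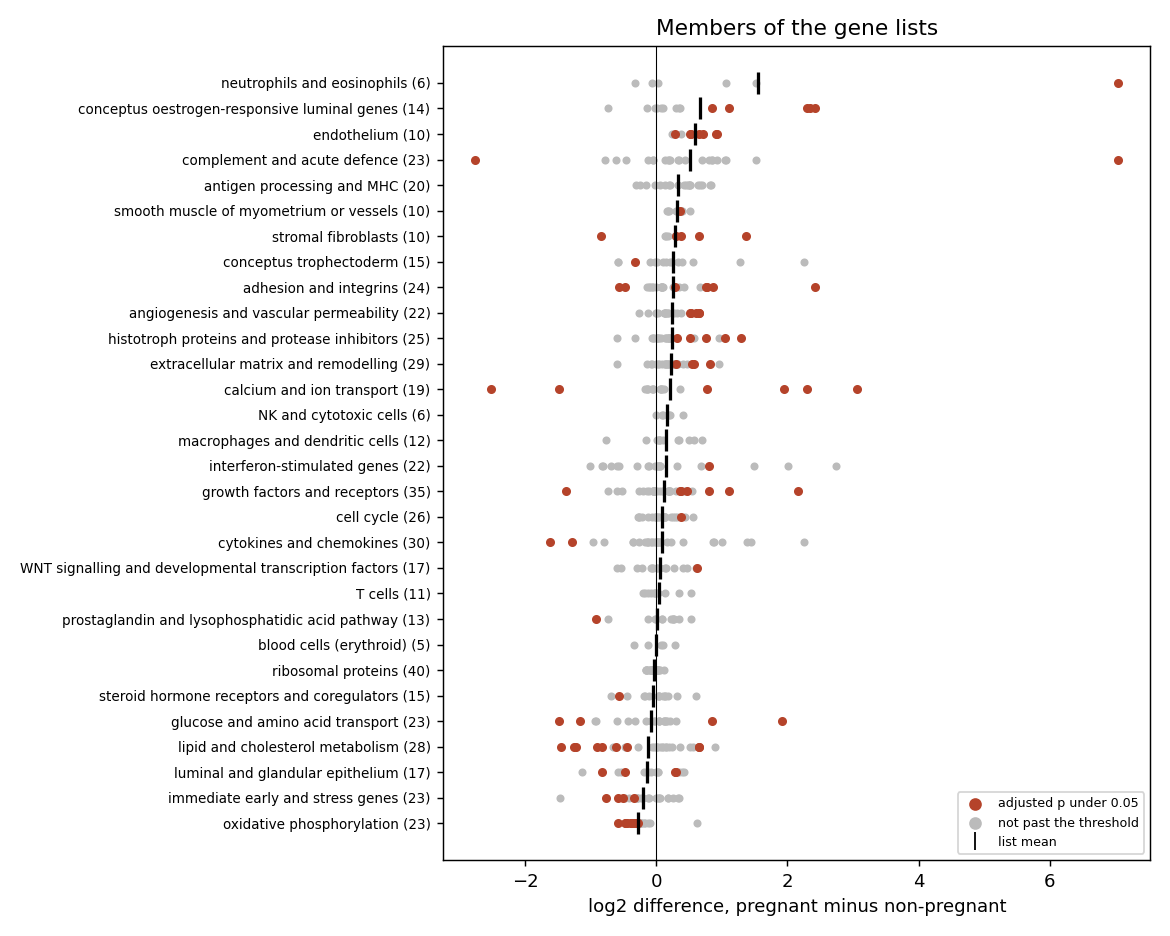
Log2 difference, pregnant minus non-pregnant, of each measured member of the 30 tested lists, with the number of measured members in brackets and a bar at the list mean. All 7 called endothelium members lie above 0 and all 13 called oxidative phosphorylation members below 0.

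Few immune genes passed the threshold. Of 22 measured interferon-stimulated genes, STAT2 rose by 0.81 ± 0.22 on the log2 scale (SE, adjusted p = 0.0416, higher in 5 of 6 sows) and 0 passed when adjusted over the list alone; the list had adjusted p = 0.600, and the STAT2 call ended without any 1 of 9 sows (adjusted p up to 0.0979). IRF1 differed by 1.48 ± 0.56 (adjusted p = 0.126) and passed without non-pregnant sow 7 or pregnant sow 8, at adjusted p of 0.0373 and 0.0266. None of 20 genes of antigen processing and MHC was called, over all genes or adjusted over the list alone (0), and SLA-2, CIITA, CD74 and B2M differed by 0.45, 0.43, 0.66 and -0.02. The list antigen processing and MHC was called (adjusted p = 0.0185, adjusted p = 0.674 with an estimated correlation), and its call ended without non-pregnant sow 5 (0.0829) or 9 (0.0547) or pregnant sow 6 (0.0737) or 12 (0.111). Of 23 complement and acute defence genes S100A9 rose and DEFB1 fell, 2 and 2 when adjusted over the list alone, and the list was called at adjusted p = 0.0166 (adjusted p = 0.552 with an estimated correlation), with adjusted p = 0.0537 without non-pregnant sow 11. Of 30 cytokines and chemokines, IL1A fell by 1.28 ± 0.19 (adjusted p = 0.00584) and the epithelial chemokine CCL28 by 1.62 (adjusted p = 0.0474, lower in 5 of 6 sows), a call that ended without any 1 of 10 sows (adjusted p up to 0.108); adjusted over the list alone 3 rose and 2 fell. Without non-pregnant sow 7, SLA-2, CIITA and CD74 passed, at adjusted p of 0.00661, 0.0164 and 0.0259. Without that sow 4 interferon-stimulated, 8 MHC, 9 complement and 4 cytokine genes rose, and without pregnant sow 8 the numbers were 4, 2, 3 and 3. Non-pregnant sow 7 had the highest mean of its group on each of these lists. Leaving it out raises their mean differences by construction, so the calls gained without it are no separate support for a rise. Without pregnant sow 12, 3 complement genes rose. The count of complement falls was 2 without non-pregnant sow 7 or pregnant sow 8 or 12 and 0 without any 1 of 7 others. In addition 1 MHC gene fell without pregnant sow 8 and 1 interferon-stimulated gene without pregnant sow 12.

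Non-pregnant sow 7 stood apart in immune lists. Its mean of the macrophage and dendritic cell markers was 1.69, against -0.398 to -0.26 in the other non-pregnant sows; its MHC mean was 1.09 against -0.315 to -0.134, and its complement mean 1.18 against -0.41 to -0.107. None of the 12 macrophage, 11 T cell or 6 NK cell markers was called, and adjusted over the list alone the counts were 0, 0 and 0. Over all sows these lists had adjusted p of 0.331, 0.563 and 0.138, and without non-pregnant sow 7 they had adjusted p of 0.000287, 0.0185 and 0.0185 at the preset correlation. With an estimated correlation, which was run over all sows only, their adjusted p was 0.903, 0.911 and 0.552, and it was 0.911 for the cytokine and 0.552 for the neutrophil list. The cytokine list had adjusted p = 0.506 and 0.00674 without it, and the neutrophil list, in which only S100A9 of 6 members was called (also 1 when adjusted over the list alone), adjusted p = 0.121 and 0.0466 without it (0.0435 without pregnant sow 12). Sow 7 had the highest mean of the non-pregnant sows on the macrophage, T cell, NK cell, cytokine and neutrophil lists. Leaving it out raises these differences by construction, so the lower adjusted p is no separate support for a rise in pregnancy. The median of the T cell list was -0.02, its mean 0.04, and its test pointed up. None of 5 erythroid markers was called, and 0 when adjusted over the list alone (list adjusted p = 0.939, median 0.07, mean -0.00, test up). The cytokine list had a median of 0.01 and a mean of 0.08, and camera pointed up and fry down. Without non-pregnant sow 7, 3 macrophage, 1 T cell and 1 NK cell marker rose and 1 erythroid marker fell. Without pregnant sow 12, 3 neutrophil markers and 1 T cell marker rose and 1 erythroid marker fell.

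On the list of conceptus trophectoderm genes, none of 15 rose and CYP19A3 fell by 0.33 (adjusted p = 0.0425), with 1 of its 7 other probe sets showing the same sign; adjusted over the list alone 2 fell, and the list had adjusted p = 0.506. The CYP19A3 call ended without any 1 of 9 sows (adjusted p up to 0.100). Its mean was 1.63 in pregnant sow 10 and at most 0.318 in the other pregnant sows. The oestrogen receptor ESR1 fell by 0.58 ± 0.14 on the log2 scale (SE, adjusted p = 0.0257, no overlap between the groups), and the progesterone receptor PGR differed by -0.11 (adjusted p = 0.398). ESR1 was the only call among 15 steroid receptors and coregulators, where 3 fell when adjusted over the list alone (list adjusted p = 0.951, median 0.04, mean -0.04, test up). The ESR1 call ended without pregnant sow 2, 6 or 10 or non-pregnant sow 5 or 9, with adjusted p up to 0.0654. The prostaglandin E synthase PTGES fell by 0.92 ± 0.20 (adjusted p = 0.0177) and PTGS2 differed by -0.74 (adjusted p = 0.189); PTGES was the 1 call among 13 genes of its list, over all genes and adjusted over the list alone (list adjusted p = 0.359). FZD4 rose by 0.62 (adjusted p = 0.00695) as the 1 call among 17 WNT and developmental genes, where 2 rose and 2 fell when adjusted over the list alone (list adjusted p = 0.359). Of 26 cell cycle genes the inhibitor CDKN1B rose by 0.38 (adjusted p = 0.0245; up to 0.0621 without any 1 of 4 sows), 1 gene rose when adjusted over the list alone, and the list had adjusted p = 0.0952, and 0.0449, 0.0419 and 0.0281 without pregnant sows 6, 8 and 12 and 0.0435 without non-pregnant sow 7, with adjusted p = 0.674 with an estimated correlation over all sows. Of 17 epithelial markers KRT8 and CLDN7 fell, by 0.83 and 0.47, and MUC1 and SPINT2 both rose by 0.29, and 3 rose and 5 fell when adjusted over the list alone (list adjusted p = 0.888). The calls of KRT8, CLDN7, MUC1 and SPINT2 ended without any 1 of 9, 6, 8 and 9 sows, with adjusted p up to 0.102. Without non-pregnant sow 7 and pregnant sows 8 and 12, 2, 3 and 3 steroid receptors and coregulators fell, and 1 rose without non-pregnant sow 7. WNT and developmental rises numbered 2 without non-pregnant sow 5 or pregnant sow 8, and falls 2, 2 and 1 without non-pregnant sow 7 and pregnant sows 8 and 12. Cell cycle rises numbered 2 without non-pregnant sow 7 or pregnant sow 12, and 2 trophectoderm genes fell without pregnant sow 12. None of 40 ribosomal protein genes was called, and 0 when adjusted over the list alone (list adjusted p = 0.506). Lists with fewer than 5 measured members were not tested: of 2 mast cell markers KIT rose by 0.68 (adjusted p = 0.0123), also when adjusted over the list alone, and none of 4 ciliated, 3 lymphatic or 4 B and plasma cell markers was called (0 when adjusted over the list alone).

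**Figure D4:**
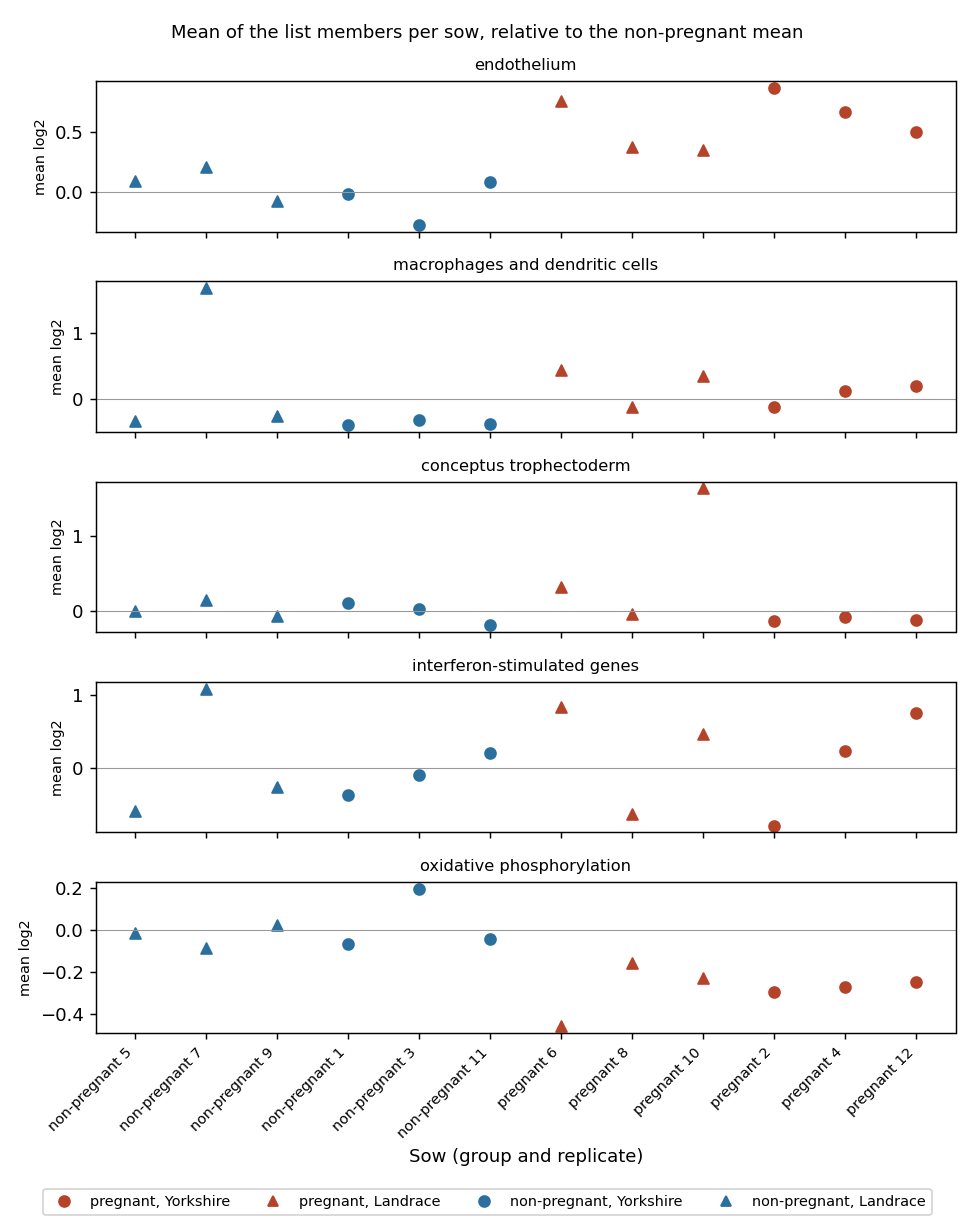
Mean log2 value of the members of 5 lists in each sow, relative to the non-pregnant mean, with colour for pregnancy and shape for breed. Endothelium and oxidative phosphorylation separate the groups, non-pregnant sow 7 lies at 1.69 for macrophages, and pregnant sow 10 lies at 1.63 for trophectoderm.

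Over all probe sets, 1892 of 23999 were called for pregnancy (limma, 7.88%), 947 higher and 945 lower, with a median absolute log2 difference of 0.526, and 252 changed at least 2-fold. With 1 probe set per gene, 310 genes were higher and 506 lower, and 862 called probe sets had no single symbol. The camera test called 12 of 30 lists, 0 with an estimated correlation (4 at unadjusted p under 0.05), and fry called 6. The number of called probe sets was 951, 1071, 1001 and 1257 without pregnant sow 2, 4, 6 or 10 and 1001, 1166 and 1039 without non-pregnant sow 3, 5 or 9. It was 3640 with arrays weighted, 2888 with the first residual component as a covariate and 1165 without the breed term. The residual component comes from the residuals of the same fit. It leaves the differences unchanged and lowers the remaining spread, so a higher count was near certain in advance. The array weights also come from residuals of this design, and arrays far from their group count less, so that higher count is no separate support.

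The second comparison set the breeds against each other. The largest breed differences were in C1QTNF3, LOC100621607, VNN2, STC1 and LOC100158115, and of the 10 genes given here STC1, NAAA and SST were also called for pregnancy. C1QTNF3, a member of the C1q and TNF family, was at 4.39 in Landrace and 8.68 in Yorkshire sows, a log2 difference of -4.29 ± 0.67 (SE, adjusted p = 0.00446), with 4 Landrace sows at 3.13 to 3.94, below the lower quartile of every array, and LOC100621607 differed by -3.31 ± 0.35 (adjusted p = 0.000457). The hormone somatostatin (SST) was lower in Landrace sows at -1.64 ± 0.29 (adjusted p = 0.00782), and LOC100158115 and NAAA at -2.17 and -1.67. AGT, the angiotensin precursor, was higher in Landrace sows by 2.12 ± 0.38 (adjusted p = 0.00873), WFDC2 by 2.07 ± 0.35 (adjusted p = 0.00664) and TMEM26 by 1.69 ± 0.23 (adjusted p = 0.00214), though the other probe set of TMEM26 had the opposite sign. VNN2 and STC1 were higher by 2.58 (adjusted p = 0.0290) and 2.21 (adjusted p = 0.0486). In all, 1236 probe sets were called for breed (limma, n = 6 per breed), 533 higher and 703 lower in Landrace sows, and 820 without pregnant sow 10. The sign of RNA integrity also differed between the breeds, with a GAPDH difference of -0.421 in Landrace less Yorkshire sows, and no test separated breed from RNA integrity. The calls of VNN2, STC1, LOC100158115 and NAAA ended without any 1 of 8, 10, 10 and 5 sows, with adjusted p up to 0.104. The lists of complement and of ribosomal proteins were higher in Landrace sows (adjusted p = 0.0214 each) and those of matrix and stroma lower (adjusted p = 0.0242 and 0.0407), and each reached adjusted p = 0.892 with an estimated correlation.

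The last comparisons asked whether pregnancy acts alike in both breeds. Within Landrace sows 247 probe sets were called (limma), 132 higher and 115 lower, and 232 of them (93.9%) had the same sign within Yorkshire sows. Within Yorkshire sows 0 were called by limma, with 3667 at unadjusted p under 0.05 where 1200 would be expected by chance and a smallest adjusted p of 0.0557. The difference between breeds was tested by the interaction, which called 0 probe sets (963 at unadjusted p under 0.05, smallest adjusted p = 0.322). Of the lists, 12 were called for the interaction by camera and 0 with an estimated correlation (smallest adjusted p = 0.0661). The gene with the smallest interaction p was HSD17B2, which inactivates oestradiol, with log2 differences of 1.10 within Yorkshire and -1.48 within Landrace sows (interaction -2.57, adjusted p = 0.444, and 0.0189 without pregnant sow 12). MCUB and PTGFR followed, with interactions of -0.83 and 1.36 (adjusted p = 0.919 each). Log2 differences of the breeds correlated at r = 0.622 (Spearman's rho = 0.505) across probe sets, which are not independent replicates. Without pregnant sow 12 the counts were 1381 within Yorkshire, 560 within Landrace and 18 for the interaction. The Yorkshire count was 35, 63 and 1 without non-pregnant sow 7, pregnant sow 8 and pregnant sow 10. The Landrace count was 146, 47 and 17 without non-pregnant sow 1, 5 or 9 and 31, 555 and 13 without pregnant sow 6, 8 or 10, and the interaction count was 1 without non-pregnant sow 5. Weighting the arrays gave 3142 calls within Yorkshire, 1176 within Landrace and 2 for the interaction. The weights come from the residuals of the same design, so arrays far from their group count less. The higher counts are no separate support.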

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

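The tests of the 3 patterns weighed here were chosen only after the result was seen, and the counts of other splits of the sows were planned before. Among 310 groups of 6 sows that were examined, over named genes and list means, 33 held 1 sow far from the rest, where the gap to the nearest other sow was a larger share of the range than chance usually gives, and chance gives about 1 in 20, or 15.5. Of the 33, 20 were non-pregnant sow 7, 5 pregnant sow 12 and 5 pregnant sow 8, with 1 each for non-pregnant sow 3, pregnant sow 10 and pregnant sow 4.

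Non-pregnant sow 7 stood apart in the non-pregnant group. The gap as a share of the range was 0.879 for S100A9, 0.834 for FGL2, 0.799 for DEFB1, 0.841 for RAB26, 0.784 for BCAT1, 0.682 for VWA5A, 0.843 for SLA-DRA, 0.890 for CD163, 0.838 for SPP1, 0.776 for IRF1 and 0.849 for CD74. For list means it was 0.871 for MHC, 0.738 for adhesion, 0.895 for cytokines, 0.808 for complement, 0.663 for cell cycle, 0.934 for macrophages, 0.785 for T cells, 0.741 for NK cells and 0.768 for neutrophils.

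More macrophages and dendritic cells in the tissue may account for the immune transcripts of that sow but stay open, since the sow was highest for 11 of the 12 measured markers, the same list that set it apart, with CD163 at 11.1, C1QC at 11.4 and SLA-DRA at 11.9; 10 of the markers were above the array median in non-pregnant sows and 3 stand on another list. The erythroid mean of 0.0426 lay within -0.167 to 0.217 of the other non-pregnant sows, and HBB, at 7.58, lay below their 7.92 to 8.19. These values argue against more erythroid RNA in this sow. Only 5 erythroid markers were measured, and the rule on HBB was set after its value was seen. Blood left in the tissue was therefore not excluded as a source of the immune transcripts. An exchange of labels with pregnant sow 8 gave 824 calls, and with pregnant sow 6 or 10 it gave 0, against 1892 with the labels as given. Fewer calls argue against an exchange but do not exclude one. Sows 7 and 8 lay at 0.530 and 0.487 on the scale given next, near the middle between the groups. The macrophage mean lay 1.24 above the highest of the pregnant sows, so a wrong label alone would leave the immune transcripts unexplained. That mean set the sow apart, so it cannot decide the label, which stays open. Over probe sets called without it the array lay at 0.530 between the non-pregnant mean at 0 and the pregnant mean at 1 (SD 0.138 among the other 5 non-pregnant sows). It was nearer to the pregnant mean for 41.5% of them. NPY at 3.56 and PDK4 at 8.47 were as in non-pregnant sows. The endothelium mean of 0.209 and the oxidative phosphorylation mean of -0.0874 lay outside the pregnant range (0.351 to 0.867 and -0.456 to -0.158). These genes and lists were picked from fits that counted the sow as non-pregnant, so they cannot decide its label. The design gives no biological explanation for a single sow, and none beyond the cell markers was examined.

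Pregnant sow 12 stood apart in pregnant sows for S100A9 (0.855), STC1 (0.630), ITGB5 (0.6255), HMGCS1 (0.627) and KLK1 (0.665), nearer to the non-pregnant values for S100A9, STC1, ITGB5 and HMGCS1. An exchange of labels with a non-pregnant Yorkshire sow gave at most 421 calls against 1892, which argues against an exchange but does not exclude it. A wrong label of this array alone could not be excluded and may apply, since the array lay at 0.368 on the same scale, with an SD of 0.293 among the other 5 pregnant sows. Its neutrophil mean of 0.258 lay below their 1.27 to 2.36. That mean also lay above the -0.554 to -0.114 of the non-pregnant sows other than sow 7, which was at 1.34. S100A9, for which sow 12 stood apart, is on the neutrophil list, so this mean is no separate support for a wrong label. PDK4 at 9.46, the endothelium mean of 0.499 and the oxidative phosphorylation mean of -0.247 lay outside the range of the non-pregnant sows (8.22 to 8.72, -0.277 to 0.209 and -0.0874 to 0.193). This gene and these lists were picked from fits that counted the array as pregnant, so they cannot decide its label. RNA of poorer quality stays open as well, since the GAPDH difference of 1.55 and the actin difference of 1.01 lay within the 1.15 to 1.59 and 0.919 to 1.45 of the other pregnant sows, which decides nothing, and no biological explanation, such as a weaker response, was tested.

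Pregnant sow 10 stood apart in the trophectoderm list (0.742). Conceptus cells left on the endometrium may account for this but stay open, since the sow was highest for 9 of 15 members of the same list that set it apart, with IFNG at 12.6, against 8.21 in pregnant sow 6 and at most 4.41 elsewhere, and PAG6 at 11.2, against 5.92 in pregnant sow 6 and at most 4.56 elsewhere. The horns had been flushed, 5 of the members were above the array median in non-pregnant sows and 4 stand on another list. The probe set that stood for CYP19A3 was not raised, at 7.89. Most other probe sets of CYP19A3 had the opposite sign for pregnancy, and their values in this sow are not given here. CYP19A3 therefore decides nothing about conceptus cells. Against more T cells or NK cells as the source of IFNG, the larger of the list means lay at -0.384 from that of non-pregnant sow 7, which was highest on both lists with IFNG at 4.41, and the T cell mean of 0.118 was below those of pregnant sows 4 and 6 (0.14 and 0.265), but the NK means of pregnant sows 6 and 10, 0.441 and 0.247, were above all others except that of sow 7, and IFNG made by the cells present stays open. No biological explanation was tested.

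Pregnant sow 8 stood apart for FGF12 (0.698), TPPP3 (0.730), and the stress (0.704), ribosomal (0.706) and erythroid (0.646) lists. Pregnant sow 4 stood apart for ITGAV (0.683) and non-pregnant sow 3 for the ciliated list (0.787).

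By the camera test of the interaction at the preset correlation, the pregnancy effect was called different between the breeds for 12 lists. It was lower in Landrace than in Yorkshire sows for oestrogen-responsive genes (adjusted p = 0.0165), histotroph (0.00106), adhesion (0.0355), angiogenesis (0.00106), cytokines (0.0128), complement (0.00176), lipids (0.0357), matrix (0.0229), stress genes (0.00485), endothelium (0.00176) and macrophages (0.0171), and higher for trophectoderm (0.0271). With an estimated correlation 0 lists passed (smallest adjusted p = 0.0661), and at the preset correlation 9 passed without non-pregnant sow 7 and 9 without pregnant sow 12. The trophectoderm mean was 1.63 in pregnant Landrace sow 10 and at most 0.318 in the other pregnant sows, and this test was not repeated without sow 10. In non-pregnant Landrace sow 7 the macrophage, cytokine and complement means were 1.69, 1.33 and 1.18. Other splits of the sows were not tried for this count of lists, so chance was not excluded for it.

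Other splits of the sows asked how often chance gives as many calls, taking the labels as given. For pregnancy 1 of 100 splits, the real one, gave as many as 1892 calls. The highest other, which exchanged non-pregnant sow 7 and pregnant sow 8, gave 824. For breed 1 of 100 splits, the real one, gave as many as 1236, and the highest other gave 0. Chance alone is therefore unlikely for both counts, though 100 splits cannot exclude it. For the interaction the real count was 0, which each of the 100 of 100 splits reaches by construction, so the splits say nothing about chance. The highest other gave 525 and grouped pregnant sows 2 and 4 and non-pregnant sow 1 with non-pregnant sows 5, 7 and 9, so that pregnancy entered with opposite signs in the breeds and the interaction added up their pregnancy effects, that of Yorkshire sows in part. For the 12 called lists 23 of 100 splits gave as many and the highest other 19, so chance was not excluded for the number of lists. Within Yorkshire (10 of 10 splits, real 0, highest other 15) and within Landrace (1 of 10, real 247, highest other 104) the splits are too few for a share under 0.05.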

How the results depend on the processing

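The settings that left out sows 7 and 10 together and HSPA8 from the stress list were chosen after seeing the data. No paired analysis was run because the labels name no pairs, though the order of the replicate numbers leaves a pairing possible. A setting that also left out pregnant sow 12 was run and is not reported, since it would choose a sow by its outcome. Pregnancy calls (1892) were 3640 with arrays weighted, 1165 without the breed term, 2888 with the residual component, 323 at adjusted p under 0.01, 777 at 1.5-fold or more, and 951 to 2626 leaving out 1 sow. The residual component lowers the spread by construction, so its higher count is no support. Higher counts with weights are none either, since the weights come from residuals of the same design. Second normalization by loess gave 1939, centring 1957 (42.4% higher against 50.1%), leaving out dim probe sets 2079, trend and robust prior 1735, the average of the breeds 1727 and sows 7 and 10 out 1619. Breed calls (1236) were 603 without sows 7 and 10 and 820 to 1342 leaving out 1 sow. Within Yorkshire (0) counts were 59 without dim probe sets, 3142 with weights, 11 with the arrays of that breed alone, 4 without sows 7 and 10 and 0 to 1381 leaving out 1 sow. Within Landrace (247) they were 389, 1176, 19, 68 and 13 to 560. The interaction (0) gave 2 with weights and 0 to 18 leaving out 1 sow. Called lists (12) were 0 with an estimated correlation, 6 with fry and 11 to 18 leaving out 1 sow. Of 80 called named genes, 78 stayed called with loess, 77 with centring, 58 without the breed term and 51 to 75 leaving out 1 sow.

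Results that were not called changed direction in some settings, where the direction of a list is that of its test and its value is the mean over its members. Without sows 7 and 10 the PDPN pregnancy difference was 0.101, the FGF7 pregnancy difference 0.0210, the HSD17B2 pregnancy difference 0.0740 and the B2M pregnancy difference 0.0110. With weights PDPN was at 0.147 and B2M at 0.00665. With loess the KLK1 pregnancy difference was -0.0184, B2M was at 0.0376, and the test changed direction for the list ribosomal proteins (0.0109) and the list blood cells (erythroid), whose mean of -0.0171 kept the sign of -0.00275 over all sows, and with centring KLK1 was at -0.0138. Without dim probe sets the test changed direction for the list steroid hormone receptors and coregulators (mean -0.0728), the list luminal and glandular epithelium (-0.137) and the list conceptus trophectoderm (-0.277), and with fry for steroid receptors (-0.0427), the list cytokines and chemokines (0.0832) and erythroid cells (-0.00275). Leaving out 1 sow changed the direction of the test for steroid receptors and epithelium, while their means kept their sign (-0.0668 to -0.0206 and -0.191 to -0.0718), and for the list interferon-stimulated genes (-0.00557 to 0.368) and erythroid cells (-0.102 to 0.0556). It gave -0.234 to 0.199 for PDPN, -0.195 to 0.902 for the SPP1 pregnancy difference, -0.483 to 0.183 for FGF7, -0.0508 to 0.103 for KLK1, -0.00398 to 0.772 for the S100G pregnancy difference, -0.430 to 0.0462 for HSD17B2 and -0.0524 to 0.0388 for B2M. The cause was not tested. For the named genes of the pregnancy effect under the settings other than leaving out 1 sow, 911 values kept direction and side of the threshold, 54 lost the call, 17 gained it and 9 changed direction. Signal over background limits what dim probe sets can show.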

Other observations

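The genes in this part were chosen after their values were seen, and no test was run on them beyond the fits already described. Several interferon-responsive genes differed among the pregnant sows. The guanylate-binding protein GBP1 was at 10.5, 12, 11.7 and 11.3 in pregnant sows 4, 6, 10 and 12 and at 7.96 and 7.6 in pregnant sows 2 and 8, while non-pregnant sow 7 was at 10.5 and the other non-pregnant sows at 6.47 to 7.32 (adjusted p = 0.0824 over all sows). GBP2 was at 8.06, 10.3, 9.68 and 8.94 in pregnant sows 4, 6, 10 and 12 and at 6.23 and 6.51 in pregnant sows 2 and 8. MX1 and ISG15, both interferon-induced antiviral genes, were also lowest in pregnant sows 2 and 8, with MX1 at 8.61 and 8.66 and ISG15 at 7.71 and 7.98. The other pregnant sows, at 9.1 to 10.5 for MX1 and 9.09 to 10.1 for ISG15, lay within the range of the non-pregnant sows, 9.23 to 10.9 and 8.87 to 11.2, except for MX1 in pregnant sow 10. USP18 did not follow the division, at 7.56 and 7.46 in pregnant sows 2 and 8 and 7.71 and 7.55 in pregnant sows 6 and 10.

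S100A8, the usual partner of S100A9, was at 8.42, 7.77 and 7.17 in pregnant sows 2, 4 and 8 and at 5.28, 5.17 and 4.57 in pregnant sows 6, 10 and 12 (adjusted p = 0.167), and S100A12 was at 6.37, 6.95 and 5.65 in pregnant sows 2, 4 and 8. PDK4, a kinase that inhibits pyruvate dehydrogenase, had the smallest p for pregnancy among genes with a symbol and lies outside the rule for named genes, at 9.29 to 10.5 in pregnant and 8.22 to 8.72 in non-pregnant sows (log2 difference 1.60, adjusted p = 0.00185). In non-pregnant sow 7 the chemokine CXCL13 was at 12.6, CXCL8 at 8.64, CHI3L1 at 10.3, HP at 9.49, SOD2 at 12.1 and MMP7 at 9.65. In pregnant sow 10 HAND1 was at 8.26, DPPA5 at 8.12 and IL1B at 9.52, and IL1B was at 9.74 in non-pregnant sow 7.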
